A study of Mus musculus with 65 samples.

How the data were processed

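The series holds 65 single mouse cells from the cochlea at postnatal day 10. Each library is 1 outer hair cell (OHC) that was picked by hand after papain and protease digestion of the tissue. Per the labels' protocols, cDNA was made with the Smart-Seq HT kit, which copies full-length transcripts and adds no molecular identifiers, and libraries were made by tagmentation with a TruePrep kit. In both groups a FlpO recombinase under Slc26a5 control switched on a nuclear green fluorescent reporter, by which the OHCs were recognised. The 48 cells of the WT group came from mice with that driver and reporter alone. The 17 cells of the CKO group came from mice that also carried Atoh1-Cre and floxed Casz1 alleles on both chromosomes, so the groups differ in the presence of Cre as well as in Casz1. The protocol text shared by all samples speaks of picked inner hair cells and induced OHCs, while titles and the series design name OHCs; the titles and design were followed.

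The authors deposited 1 table of whole-number counts per gene for the 65 cells. Per the submitters' processing notes, reads were handled with HISAT2 2.2.1, StringTie 2.2.1 and featureCounts 2.0.1 on the mm10 build; which of the last 2 tools gave the counts, the annotation release, the strand setting and any filter on reads or cells are not given in the sources used here. The table lists 55292 gene symbols, of which 53292 (96.4%) are in GENCODE release M21 for GRCm38 (mm10), which was used here only for positions and for overlaps between genes. All columns matched the title of 1 sample. Because the strand setting is not given, reads of genes with overlapping exons on opposite strands could not be told apart.

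The labels name no animal, litter or culture, so each genotype was treated as 1 sample, and cells were not used as replicates. No test was run and no p-value is given. Counts were summed over the cells of a group and divided by the summed total to give CPM, counts per 1000000 counts. Sums carry exact Poisson intervals, the log2 ratio of CKO over WT carries an exact conditional (Clopper-Pearson) interval, and shares of cells carry exact binomial intervals, all at 95%. These intervals cover counting error only: reads without molecular identifiers are not independent molecules, and differences between cells and animals are not included, so they are far narrower than the real uncertainty. A gene with no count in a group was set to 3 counts over that group, and its ratio is given as a bound. As a description of overlap between the cells, the share of the 816 pairs of 1 CKO and 1 WT cell in which a given group had the higher CPM is given, with ties counted as 0.5.

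Fixed beforehand as well were 31 gene lists and the rule for named genes. The rule takes Casz1; the 12 genes with the highest and the 12 with the lowest log2 ratio among those with at least 20 CPM in the higher group, a count in at least 50% of its cells, and a pair share of at least 75%; up to 4 members of each list with the largest absolute ratio; and a fixed set of hair cell genes (Slc26a5, Ocm, Ikzf2, Insm1, Tbx2, Slc17a8, Otof, Gata3, Myo7a, Pou4f3 and Sox2). Some genes that the rule names are not reported here. Predicted and unnamed genes were passed over, 4 among the higher and 1 among the lower genes. A list member counted as measured with at least 5 CPM in the higher group, which 10842 genes of the table reached. An order-statistic interval of the median log2 ratio is printed for some lists. The median itself was given for lists with at least 3 measured members, with its percentile among 10000 random lists of the same size drawn from 20 bins of expression. The percentile describes these libraries only.

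No cell was removed from the main values. No doublet caller was run, because cells were picked singly. Of the 2080 pairs of cells none held identical columns, and the highest correlation of log2(CPM + 1) across genes was 0.68. A cell was said to have the Xist pattern with at least 10 counts of Xist and fewer than 10 over Ddx3y, Uty, Kdm5d and Eif2s3y, and the Y pattern in the reverse case. These patterns were not used to assign cells to groups; they served to recompute the comparison between cells of 1 pattern.

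Other settings, fixed before the data were examined, were the mean or the median of per-cell CPM, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios factors, a total without mitochondrially encoded and ribosomal protein genes, leaving out the cell with most counts, a filter on cell quality, thinning of each cell to 1 depth, other filters on list members, the mean over a list, and detection at 10 counts. Chosen after seeing the data were the comparison of Xist-pattern cells, of cells with a total of at least 10000000, of cells with at least 6000 genes, leaving out each cell in turn, leaving out the 4 CKO cells with the highest mean log2(CPM + 1) over the measured genes of the stress list, and comparing the CKO cells with WT cells 1 to 11, 12 to 45 or 46 to 48 alone.

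The ratio script was tested on simulated cells with 200 changed genes. At a true log2 ratio of 2, the 100 raised genes came out at a median of 2.01 and 66% of them passed the pair share; at -2, the 100 lowered genes came out at -2.04 and 58% passed. Among 6177 unchanged genes the central 95% of ratios ran from -1.34 to 1.09, and 0.178% passed the pair share. Only genes with at least 20 CPM in WT cells were simulated, so genes sparse in or nearly absent from WT cells were not covered. Simulated cells were drawn independently around 1 mean per gene, without differences between animals, sexes or runs. These shares are therefore no error rates for the real groups. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3.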

Results

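Outer hair cells amplify sound in the cochlea by changing length through the motor protein prestin, the product of Slc26a5. Casz1 encodes a zinc finger transcription factor, and the series asks what its loss does to OHCs and their survival. Transcripts were counted in 48 single WT OHCs and 17 single OHCs labelled Casz1 CKO, all at postnatal day 10. The WT cells held 547934202 counts in all, with a median of 11520603 per cell and a range of 7458126 to 17107710. The CKO-labelled cells held 199812603 counts, with a median of 12269271 and a range of 8239671 to 15320549. The median number of genes detected per cell was 7586 in WT cells (quartiles 7199 and 7980) and 7417 in CKO-labelled cells (quartiles 7000 and 7753).

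Ocm, the gene of the OHC calcium buffer oncomodulin, took a median of 3.67% of counts in WT cells and 4.68% in CKO-labelled cells. Mitochondrially encoded genes took a median of 6.52% (quartiles 5.56% and 7.83%) and 4.76% (quartiles 4.02% and 5.32%), and ribosomal protein genes 2.17% and 1.94%. With 1 sample per genotype, none of the differences below has a replicate check.

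Casz1 transcripts were present in both groups. Casz1 (chromosome 4, 148804429 to 148954889 on the plus strand, GRCm38) stood at 53.3 CPM in WT cells (95% interval 52.7 to 53.9) and 46.2 CPM in CKO-labelled cells (45.2 to 47.1), a log2 ratio of -0.21 (-0.24 to -0.17). At least 1 count was found in 42 of 48 WT cells (87.5%, 74.8% to 95.3%) and in 15 of 17 CKO-labelled cells (88.2%, 63.6% to 98.5%). The median over single cells ran the other way, at 31.98 CPM in WT cells (quartiles 11.2 and 82.8) and 41.7 CPM in CKO-labelled cells (quartiles 13.0 and 69.9), and a CKO-labelled cell was higher in 49.1% of pairs. The labels do not say which exons are floxed, and its exons overlap Gm13205 on the opposite strand, so counts over the whole gene check nothing about deletion. The cells are called CKO-labelled for that reason, or CKO for short, and every direction below rests on the labels.

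The groups also differed in the sex chromosomes their cells expressed. Xist, the RNA that coats the inactive X chromosome, was at 42.5 CPM in WT cells and 144.3 CPM in CKO-labelled cells. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had 1 count over all CKO-labelled cells, while WT cells stood at 146.3 CPM for Eif2s3y and 62.7 CPM for Ddx3y. The Xist pattern was found in 9 of 48 WT cells and 15 of 17 CKO-labelled cells, and the Y pattern in 37 WT cells and in 0 of 17 CKO-labelled cells, which allows a share of up to 19.5%. In each group, 2 cells had neither, and no cell had both. The list of 5 sex-linked genes had a median log2 ratio of -12.03, a bound set by genes without a count. Genotype was therefore largely confounded with sex, and some values among Xist-pattern cells, 9 WT and 15 CKO-labelled, are given beside the pooled ones.

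The WT cells also fell into runs along their numbers. Per cell, mt-Co2 ran from 33.5 to 83.6 CPM in WT cells 1 to 11, from 229 to 644 CPM in WT cells 12 to 45, from 100 to 111 CPM in WT cells 46 to 48, and from 94.8 to 283 CPM in CKO-labelled cells. These runs were set after seeing mt-Co2, and the labels name no batch. The run 12 to 45 was itself uneven in depth: WT cells 12 to 24 had totals of 7458126 to 9842592. WT cells 25 to 45 had at least 9856905, apart from cell 42 with 8760527. These parts of the run were not compared separately. Of the 9 WT cells with the Xist pattern 8 are numbered 1 to 11, so the Xist-pattern comparison does not separate sex from these runs. Against WT cells 1 to 11, 12 to 45 and 46 to 48 in turn, the log2 ratio of Casz1 was -0.88, 0.19 and 0.17.

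**Figure D1:**
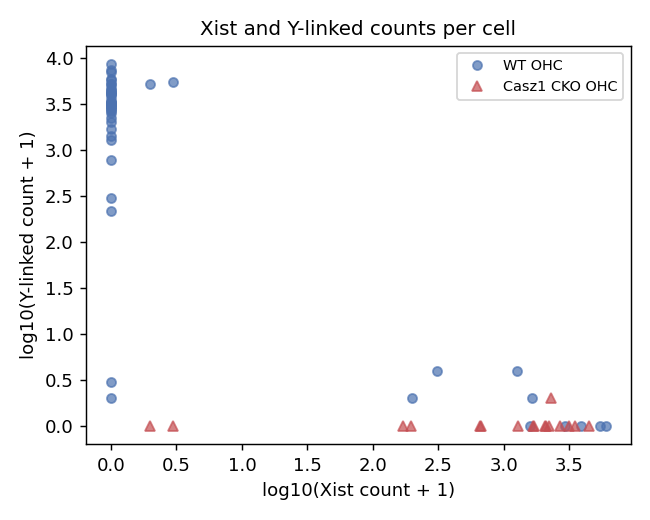
Xist counts (horizontal) and summed counts of Ddx3y, Uty, Kdm5d and Eif2s3y (vertical) in each cell, both as log10(count + 1). Each point is 1 cell, circles for 48 WT cells and triangles for 17 CKO-labelled cells; 37 WT cells lie along the vertical axis and no CKO-labelled cell does.

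Transcripts that mark OHCs were present in the CKO-labelled cells. Of 12 OHC-enriched genes, all measured, 8 were higher and 4 lower in CKO-labelled cells, with a median log2 ratio of 0.15 (percentile 95.2); the median was -0.054 against WT cells 46 to 48. Slc26a5 stood at 1175 CPM against 931 CPM in WT cells, and Ocm at 49172 CPM against 36667 CPM. Both were counted in every cell. Cells of both groups were recognised by a reporter switched on under Slc26a5 control, so the presence of Slc26a5 was favoured in advance. Ikzf2, a regulator of OHC fate whose exons overlap an opposite-strand gene, stood at 403 against 316 CPM, and Lbh at 227 against 164 CPM. Strip2 was lower, at 977 against 1410 CPM, with the WT cell higher in 73.8% of pairs. Among Xist-pattern cells the log2 ratio was -0.25 for Slc26a5, -0.13 for Ikzf2 and 0.15 for Ocm. Slc26a5 stood at 1649 CPM in WT cells 1 to 11, 576 CPM in 12 to 45 and 1332 CPM in 46 to 48, so its direction depends on the run. The Y-pattern cells among WT cells 1 to 11 held 1249 to 2187 CPM, and the Xist-pattern WT cell outside them 542 CPM.

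**Figure D2:**
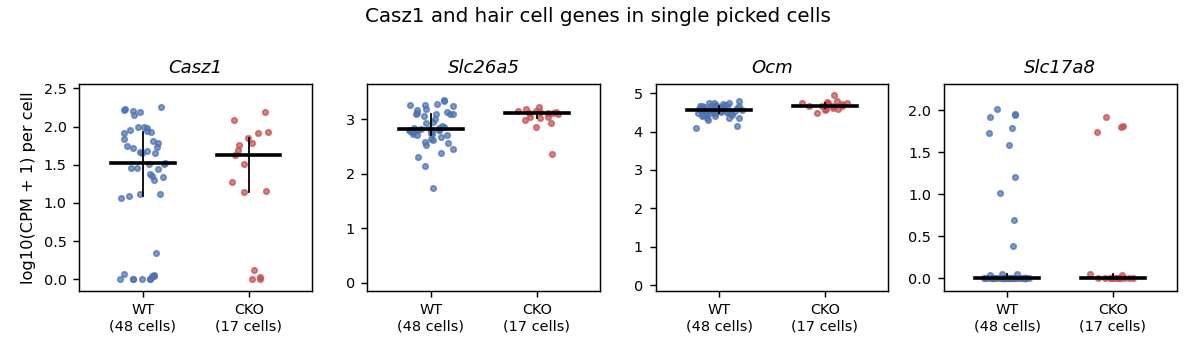
CPM of Casz1, Slc26a5, Ocm and Slc17a8 in each cell, as log10(CPM + 1), with 48 WT cells in blue and 17 CKO-labelled cells in red. Points are cells, horizontal bars medians and vertical bars quartiles; the medians are 31.98 and 41.7 CPM for Casz1 and 0 in both groups for Slc17a8.

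Genes of inner hair cells showed no common direction. Only 4 of 11 IHC-enriched genes were measured, 1 higher and 3 lower in CKO-labelled cells (median log2 ratio -0.63, percentile 4.6); over all members with a count the median was 0.14. Slc17a8, the vesicular glutamate transporter of inner hair cells, stood at 17.07 CPM against 12.1 CPM and had a count in 6 of 17 and 14 of 48 cells. Tbx2, a regulator of inner hair cell fate, had 5 counts over the CKO-labelled cells and 1 over the WT cells. Otof, whose product serves vesicle release, stood at 81.6 against 170.1 CPM. Atp2a3, a calcium pump gene on the list, was among the 12 genes with the lowest ratio, at 0.486 against 43.7 CPM.

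Genes shared by hair cells were mostly slightly lower in CKO-labelled cells. On the pan-hair-cell list 3 of 11 measured genes were higher and 8 lower, with a median log2 ratio of -0.31 (percentile 2.63), which was 0.16 among Xist-pattern cells and -0.023 against WT cells 1 to 11. Pou4f3, a transcription factor needed for hair cell survival, stood at 811 against 973 CPM. Myo7a, a myosin of the hair bundle, stood at 199 against 247 CPM (206 against 175 CPM among Xist-pattern cells), and Barhl1 at 42.8 against 71.2 CPM. Of 15 measured regulators of hair cell fate, 9 were higher and 6 lower (median 0.086, percentile 83.9). Isl1 was at 426 against 235 CPM, higher in the CKO-labelled cell in 75.1% of pairs, and Gata3, with exons that overlap other genes, was at 405 against 381 CPM (409 against 431 CPM among Xist-pattern cells). Insm1, which acts early in OHC development, was at 1.72 against 9.31 CPM and had a count in 1 of 17 and 15 of 48 cells.

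Structural and synaptic lists lay near 0. The mechanotransduction list had 8 of 15 measured genes higher (median 0.035, percentile 71.6), with Clrn1 at 222 against 146 CPM and Loxhd1 at 166 against 232 CPM. The stereocilia list had 13 of 24 higher (median 0.061, percentile 82.9). Within it Lcp1, an actin-bundling plastin, was at 606 against 246 CPM, higher in the CKO-labelled cell in 85.4% of pairs, and Xirp2 was at 353 against 159 CPM. Pls3 had no count in any WT cell and 7.85 CPM from 2 CKO-labelled cells. The ribbon synapse list had 9 of 15 higher (median 0.068, percentile 73.9), with Erc2 at 38.8 against 72.3 CPM. The efferent synapse and channel list had 5 of 10 higher (median -0.067, percentile 32.95), with Kcna10 at 853 against 477 CPM. Of 16 calcium buffers and pumps, 10 were higher (median 0.12, percentile 92.1), with Mcu at 2.95 against 9.18 CPM.

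Of 69 markers of other cell types, 16 were measured at 5 CPM or more. Of 17 supporting cell markers 6 were measured, 2 higher and 4 lower (median -0.31, percentile 16.8); Fgfr3 was at 12.2 against 40.7 CPM and Gjb6 at 1.30 against 10.2 CPM. Sox2 had no count in the CKO-labelled cells and 159 counts from 2 WT cells. Of 10 neuron markers 3 were measured (median 0.38, percentile 83.9), with Nefl at 51.0 against 32.1 CPM and Map2 at 317 against 243 CPM. Glial, macrophage and mesenchymal lists had 2 measured members each, among them Cnp at 64.2 against 118.8 CPM, C1qb at 3.03 against 18.8 CPM and Lum at 0.010 against 16.5 CPM. The endothelial list had 1 measured member, Pecam1 at 8.26 against 2.00 CPM, but at 1.00 against 4.61 CPM among Xist-pattern cells. Erythroid and stria vascularis lists had 0.

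Stress genes of the endoplasmic reticulum (ER) were higher in CKO-labelled cells. On the list of the ER and integrated stress response, 10 of 13 measured genes were higher, 8 of them by at least 2-fold, and 3 were lower. The median log2 ratio was 1.17 (percentile 100), with an order-statistic interval of -0.021 to 1.95, and 0.68 over all members with a count. Hspa5, the main ER chaperone (chromosome 2, 34771970 to 34777547), stood at 1974 CPM against 511 CPM, and a CKO-labelled cell was higher in 79.5% of pairs. Ddit3, a transcription factor induced by prolonged ER stress, stood at 289 against 72.3 CPM, Xbp1 at 170 against 42.8 CPM, and Herpud1, which acts in ER-associated degradation, at 301 against 90.9 CPM. Exons of Ddit3 overlap Mars on the opposite strand. The list's median was 1.54 among Xist-pattern cells, and 1.56, 0.86 and 0.50 against WT cells 1 to 11, 12 to 45 and 46 to 48.

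**Figure D3:**
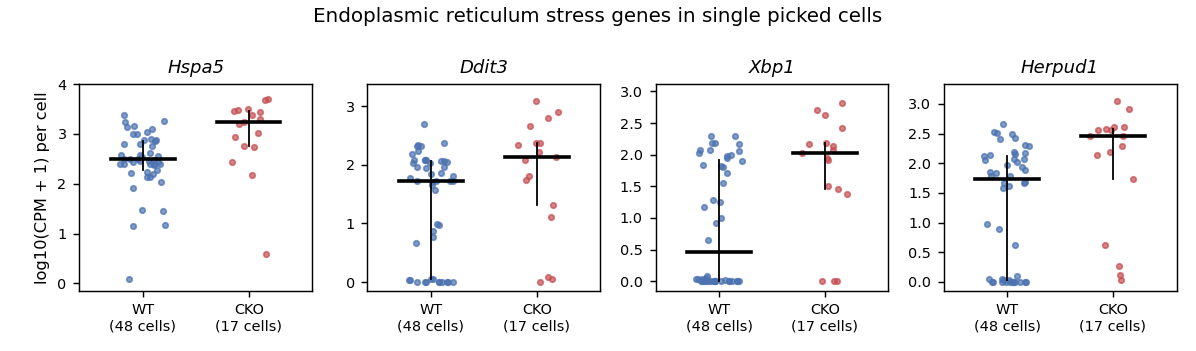
CPM of Hspa5, Ddit3, Xbp1 and Herpud1 in each cell, as log10(CPM + 1), with 48 WT cells in blue and 17 CKO-labelled cells in red. Points are cells, horizontal bars medians and vertical bars quartiles; the median of Hspa5 is 306 CPM in WT cells and 1707 CPM in CKO-labelled cells, and the groups overlap for each gene.

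Immediate early genes, which dissociation of tissue also induces, were higher as well. Of the 14 measured genes of the immediate early and dissociation list 12 were higher in CKO-labelled cells and 2 lower, with a median log2 ratio of 0.92 (percentile 99.99), 1.48 among Xist-pattern cells, and 0.82, 1.15 and 1.42 against the runs in the same order. Btg2 stood at 172 against 44.6 CPM, Dusp1 at 110 against 41.4 CPM, and Nr4a1 at 16.3 against 0.613 CPM. Not all members were higher among Xist-pattern cells: Egr1 stood at 415 against 716 CPM, Jund at 107 against 118 CPM and Ier2 at 157 against 158 CPM. Fos stood at 71.6 against 16.3 CPM there and Dusp1 at 121 against 48.6 CPM, and Nr4a1 had no count in those WT cells. Genes of p53 response and apoptosis had no common direction, with 7 of 12 higher and 5 lower (median 0.075, percentile 71.6). Bax, which permeabilises mitochondria, was at 41.1 against 25.1 CPM, while Ccng1 was at 49.5 against 93.5 CPM and Bnip3 at 34.1 against 77.1 CPM.

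Mitochondrially encoded transcripts were lower in CKO-labelled cells than in all WT cells together. All 12 measured genes had a lower CPM, with a median log2 ratio of -0.48 (interval -0.57 to -0.36, percentile 0.04); mt-Nd2 was at 2277 against 3613 CPM and mt-Nd1 at 7973 against 11859 CPM. Among Xist-pattern cells the median was -0.13, with 5 of 12 genes higher in CKO-labelled cells. Against WT cells 1 to 11, 12 to 45 and 46 to 48 it was -0.17, -0.69 and 0.11, with 5, 0 and 9 of 12 higher. Of 28 nuclear-encoded respiratory chain genes 10 were higher and 18 lower (median -0.085, percentile 32), with Uqcrc1 at 329 against 475 CPM and Ndufa9 at 209 against 137 CPM. Of 28 ribosomal protein genes 3 were higher and 25 lower (median -0.10, percentile 24.2), with Rplp1 at 273 against 567 CPM.

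**Figure D4:**
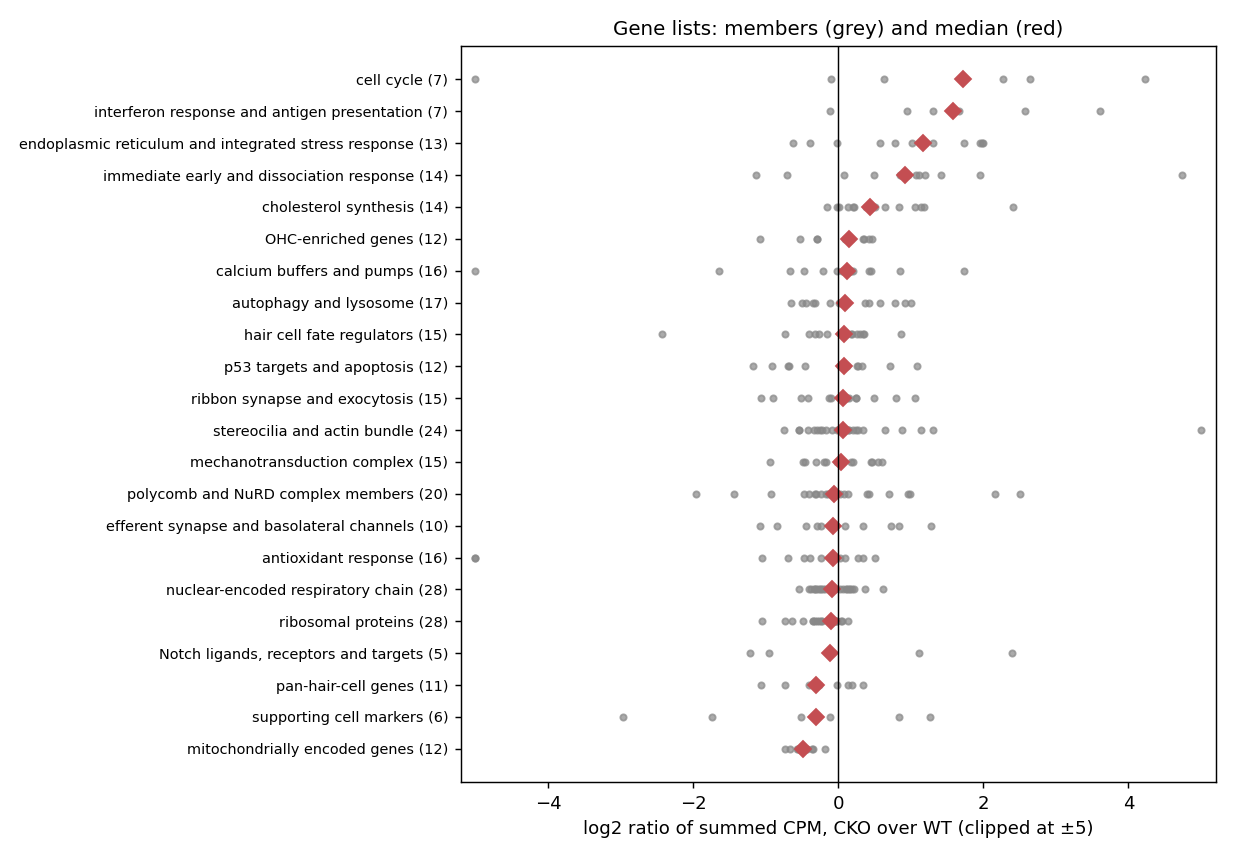
Log2 ratio of summed CPM, CKO over WT, for the members of each list with at least 5 measured members (grey points) and their median (red diamonds); the number of measured members is in brackets, values beyond 5 in either direction are drawn at 5, and the sex-linked list is left out. Medians run from -0.48 for mitochondrially encoded genes to 1.71 for the cell cycle list.

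The 12 genes with the highest ratio included several that were nearly absent from WT cells. Itgb6, an integrin subunit (chromosome 2, 60598292 to 60722643), had 1 count over all WT cells and 44.8 CPM in CKO-labelled cells, where 11 of 17 had a count (log2 ratio 14.58, 12.11 to 19.89). Mapk10, a neuronal JNK kinase (chromosome 5, 102907948 to 103211334), had 3 counts in 1 WT cell and 44.5 CPM in CKO-labelled cells. Nlgn1, a synaptic adhesion protein (chromosome 3, 25426215 to 26332460), was counted in 1 of 48 and 14 of 17 cells, at 0.155 and 66.6 CPM. Dffb, the nuclease that cuts DNA in apoptosis (chromosome 4, 153964449 to 153975126), was counted in 4 of 48 and 10 of 17 cells, at 0.12 and 46.4 CPM. At least 1 of these 4 genes had a count in every CKO-labelled cell and in 6 of 48 WT cells. This follows largely from how the genes were chosen. If the 4 were independent, 0.15 CKO-labelled cells would be expected to have none of them. Some of these counts were very low, as in CKO-labelled cell 7 with Itgb6 at 0.16 CPM and Nlgn1 at 0.24 CPM.

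Cd59a, an inhibitor of complement, stood at 109.9 against 4.46 CPM, and Nfkbia, the inhibitor of NF-kappa-B that the factor itself induces, at 912 against 146 CPM (826 against 318 CPM among Xist-pattern cells). The transcription factor Klf6 stood at 44.3 against 2.51 CPM, Gpr155 at 42.5 against 5.83 CPM, Sephs2 at 88.8 against 12.3 CPM, Tmem150c at 26.1 against 3.62 CPM, and Esyt1 at 28.7 against 5.19 CPM. Eno1b, at 27.3 against 4.07 CPM, is a near copy of Eno1 and its counts are uncertain. Exons of Nlgn1, Gpr155, Sephs2, Tmem150c and Esyt1 overlap a gene on the opposite strand.

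Among the 12 genes with the lowest ratio were the Y-linked Eif2s3y, Ddx3y and Uty. The other 9 were autosomal. Slc41a3, a magnesium transporter (chromosome 6, 90604725 to 90646412), stood at 0.025 CPM in CKO-labelled cells (5 counts) and 34.7 CPM in WT cells. Pcsk6, a proprotein convertase (chromosome 7, 65861734 to 66050386), had no count in 17 CKO-labelled cells and was at 20.1 CPM in WT cells. With 3 counts set in place of none, the bound was 1340-fold in reads, which are not independent molecules. Dnah8, a dynein chain of motile cilia, was at 2.28 against 85.5 CPM, and Atp2a3 was in this group as given above. Dixdc1 stood at 3.20 against 61.8 CPM, Wsb2 at 6.04 against 84.5 CPM, Crhbp, which binds corticotropin-releasing hormone, at 3.85 against 43.7 CPM, Artn, a ligand of the GDNF family, at 7.24 against 80.1 CPM, and Mga at 8.71 against 80.9 CPM. Among Xist-pattern cells all 21 autosomal genes of the 24 were at least 2-fold apart in the same direction. Against each run of WT cells 20 were so, Esyt1 being the exception. The genes were chosen for extreme ratios in these same cells, which favours a kept direction. Exons of Dnah8, Pcsk6 and Wsb2 overlap another gene.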

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

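Restriction to Xist-pattern cells, to cells with a total of at least 10000000 and to cells of at least 6000 genes, leaving out each cell in turn or 4 CKO cells, and comparison with runs of WT cell numbers, were chosen after seeing the data; all other settings were planned. No paired analysis was possible because replicate numbers only name cells and no test was run. Of 445 list medians under alternatives 50 differed in sign, and 17 of 25 lists changed sign at least once. The 8 that never did were the ER stress, immediate early, interferon, cholesterol, cell cycle, stereocilia, antioxidant and sex-linked lists. Over all members with a count the IHC list was 0.14 and the neuron list -0.13; against WT cells 46 to 48 the OHC list was -0.054, and the mean over its members against all WT cells -0.0032. Of 317 values of the 24 named genes 1 changed sign (Esyt1, -0.014, WT cells 46 to 48). Their choice for extreme ratios favours this. The quality filter removed 0 cells and so says nothing. TMM, median-of-ratios and the reduced total moved all log2 ratios by -0.034, -0.033 and -0.031. Genes with a median of 0 got no median of per-cell CPM.

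Casz1 had no stable size or direction. Its log2 ratio of -0.21 was -0.13 with the mean of per-cell CPM, 0.38 with their median, -0.28 after thinning to 1 depth, -0.44 in Xist-pattern cells, -0.27 in cells with a total of at least 10000000, and -0.40 without the cell holding most of its counts. Leaving out single cells gave -0.50 (without CKO cell 1) to -0.091 (without CKO cell 14). In Xist-pattern cells the list medians were 1.48 for the immediate early genes, 8.14 for the cell cycle genes, -0.13 for mitochondrially encoded genes and -0.39 for ribosomal proteins. The 8.14 was the ratio of Birc5, at 11.5 CPM against 0.041 CPM from 1 WT cell, so it rests on very few WT counts. In the same cells 16 of 127 named genes differed in sign. The mean over members was 0.51 for the stereocilia list, which Pls3 raised, and -1.12 for the antioxidant list, which Srxn1 and Cat lowered. Cholesterol synthesis was 1.59 with the median of per-cell CPM. Leaving out single cells moved ribosomal proteins between -0.16 and -0.071.

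Against WT cells 1 to 11, 12 to 45 and 46 to 48, Casz1 was -0.88, 0.19 and 0.17, and mitochondrially encoded genes were -0.17, -0.69 and 0.11, the last a reversal. Ribosomal proteins were -0.37 against WT cells 1 to 11. Against WT cells 46 to 48, only 3 cells, medians were 1.65 for IHC-enriched genes, 0.44 for the ribbon list, 3.498 for supporting cell markers, 1.26 for neuron markers, 0.69 for the p53 list, 1.42 for the immediate early genes, -1.33 for the Notch list, 5.99 for cell cycle genes, 0.21 for the nuclear-encoded respiratory chain and 0.21 for ribosomal proteins. Of the named genes with a value, 14 of 127, 4 of 128 and 23 of 125 differed in sign against the runs. Except as stated, the cause was not tested.

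Without CKO cell 1 the supporting cell list was -1.57 and the p53 list -0.30; without CKO cell 2 the Notch list was -0.86, and without WT cell 16 it was 0.18. The direction of the fate regulator, mechanotransduction, ribbon, efferent and polycomb lists turned without CKO cell 9 (-0.016), CKO cell 6 (-0.081), CKO cell 11 (-0.037), WT cell 10 (0.014) and CKO cell 6 (0.036). At 8369836 counts per cell, not reached by 5 WT and 2 CKO cells, medians of 7389 and 7147 genes were detected, and the mechanotransduction list alone changed sign (-0.046). Thinning bears on read depth only.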

Other observations

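The tests of sex pattern, single cells, several cells and runs of WT cell numbers were chosen after the results they concern had been seen. So were those of dissociation, linkage, genetic background, mixed cells and transcripts of a deleted allele. Thinning to 1 depth was planned, but the bound set for it came afterwards. Several other lists stood apart or held single genes far apart. Of 7 measured genes of interferon response and antigen presentation, 6 were higher in CKO-labelled cells (median log2 ratio 1.58, interval -0.11 to 3.60, percentile 99.2). H2-D1, a class I histocompatibility gene, stood at 52.5 against 4.32 CPM and B2m at 8.08 against 1.36 CPM. Among Xist-pattern cells B2m stood at 4.72 against 3.20 CPM, with a count in 2 of 15 and 3 of 9 cells. Of 14 genes of cholesterol synthesis 12 were higher (median 0.44, percentile 97.45), with Fdps at 15.1 against 2.86 CPM. Leaving out single cells moved this median between 0.28 (without CKO cell 11) and 0.57 (without WT cell 21). Of 7 measured cell cycle genes 5 were higher (median 1.71, interval -11.1 to 4.23, percentile 99.2), but the mean over them was 0.040. Mki67, a marker of dividing cells, stood at 135 against 21.6 CPM with a count in 9 of 17 and 15 of 48 cells, while Ccnd1 had 0.0050 against 11.1 CPM. Without CKO cell 5 the median of the cell cycle list was 0.72.

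Of 17 genes of autophagy and lysosomes 11 were higher (median 0.088, percentile 84.0), with the lysosomal proteases Ctsb at 176 against 87.8 CPM and Ctsd at 119 against 69.2 CPM. Of 16 antioxidant genes 5 were higher and 11 lower (median -0.075, percentile 41.5). Srxn1, which restores oxidised peroxiredoxins, had no count in CKO-labelled cells and 24.6 CPM from 16 WT cells, and Cat stood at 0.355 against 15.2 CPM. Of 5 measured Notch genes 2 were higher (median -0.11, percentile 42.1), with Dll1 at 18.6 against 3.54 CPM and Hes6 at 15.9 against 36.9 CPM. Of 20 polycomb and NuRD members, complexes that modify chromatin, 10 were higher and 10 lower (median -0.061, percentile 46). Chd3 stood at 19.5 against 3.42 CPM and Mta3 at 20.7 against 55.7 CPM.

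The higher level of the ER and integrated stress list, with a median of 1.17, was set against technical explanations. The sex of the cells is argued against, since the median among Xist-pattern cells was 1.54, though 8 of these 9 WT cells are numbered 1 to 11. No 1 cell carries it, since the lowest median with any 1 of the 65 cells left out was 0.82, without CKO cell 10. Several cells together stay open: without the 4 CKO cells highest in the list (1, 6, 8 and 10) the median was 0.63, and leaving out the highest cells lowers it by construction. Thinning to 1 depth, with 5 WT and 2 CKO-labelled cells left out as shallower, gave 1.16. Random thinning leaves each gene's expected share of counts unchanged, so this cannot decide whether library depth played a part. A library batch cannot be told apart: the median was 1.56 against WT cells 1 to 11 and 0.86 against 12 to 45, but 0.50 against 46 to 48, which are only 3 cells and lie nearest to the CKO-labelled cells in mt-Co2. A response to dissociation and picking cannot be told apart from an effect of genotype, because the immediate early and dissociation list was higher too (0.92) and no handling batch is named. Loss of Casz1, the presence of Cre and a difference between animals remain open.

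The autosomal genes with the highest and lowest ratios, only some of them nearly absent from 1 group, may come from the genome of a few animals, from genotype, or both. Passenger alleles around the floxed Casz1 locus do not account for most of the 21, since 19 lie on other chromosomes than Casz1. Linkage stays open for Dffb, 5.16 Mb from Casz1, and for Artn, 30.9 Mb from it on the same chromosome. It stays open also for Eno1b, counted among the 19, because its near copy Eno1 lies 1.43 Mb from Casz1. Among Xist-pattern cells 21 of 21 kept their direction by at least 2-fold, which argues against sex alone. Against each run of WT cell numbers 20 of 21 did so, which argues against the runs alone. Both counts are limited, since the genes were chosen for extreme ratios in these same cells. Moreover, 8 of the 9 Xist-pattern WT cells are numbered 1 to 11, so sex and runs were not separated. A batch of the CKO-labelled cells alone was not tested. The genes lie on 13 chromosomes, and without the animal of each cell a difference in genetic background cannot be told apart from an effect of genotype.

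Casz1 counts not clearly lower than in WT could arise if WT cells stood among the CKO-labelled ones. In a score over autosomal genes chosen each time without the scored cell, 1 of 17 CKO-labelled cells lay nearer to the WT cells and 0 of 48 WT cells lay nearer to the CKO-labelled cells. This score can find cells from WT animals only, and a cell from a CKO animal with intact Casz1 would not be found, so such cells stay open. Transcripts of a deleted allele that are still counted over the gene stay open at a pooled log2 ratio of -0.21, which was -0.88, 0.19 and 0.17 against WT cells 1 to 11, 12 to 45 and 46 to 48, since counts per exon were not analysed here. Whether Casz1 protein was lost was not tested.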
